A study of Oryza sativa with 4 samples.

How the data were processed

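The series holds 4 samples of rice leaf RNA, 2 from plants labelled empty vector control and 2 from plants labelled OsRR6 overexpressor, each hybridised to its own single-colour array after biotin labelling, per the labels' protocols, which state about 10 µg of total RNA. Groups and replicate numbers were taken from the sample titles. The deposited table gives an intensity for each of 57381 probe sets per array on a linear scale. The software that made these intensities is not given in the sources used here, and no detection calls or scanner files were used. In the values, the mean after trimming 2% at each end was 500.1 on every array, so the authors had brought the arrays to a common level, and they were kept as deposited because these means differed by less than 10%. Global scaling of this kind fixes the mean signal of an array, so a shift of all transcripts in a group cannot be seen in the values.

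Genes were assigned from the platform annotation table that came with the series. It pairs 22436 probe sets with 1 gene and 95 with several, and 34850 are not listed in it. The 17905 genes with a probe set of their own were all found in the RefSeq gene table of assembly ASM3414082v1, used for names only, and 2458 of them have a symbol or synonym there. No genome was used, so no coordinates are given. The 33 gene lists had been written as gene identifiers and descriptions, but the tables hold symbols without descriptions, so members were matched by symbol and synonym patterns written before the values of any gene were examined, and members without a matching symbol are missing from the lists.

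A pseudocount of 3.6 (the 10th percentile of all values) was added and log2 taken, which understates the change of dim transcripts. The 123 control probe sets were left out of the tests. Probe sets whose mean log2 value lay below the median of all were left out, which kept 28629. These were compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of the spread with signal), with two-sided p-values adjusted by Benjamini-Hochberg and a threshold of 0.05. Adjusted p-values of single genes come from this test unless named otherwise, and intervals are 95% confidence intervals of its log2 change. For each list with at least 3 tested genes, camera (limma, preset correlation 0.01) compared its genes with all other tested genes, with the brightest probe set of each gene and Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation and fry were run beside it. Members past the threshold were counted over all probe sets and adjusted over the list alone. Of 2384 genes with several tested probe sets 18 had probe sets past the threshold in opposite directions.

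Genes were named by a rule set before the data were examined, which gave 126 genes. It takes OsRR6 and each measured type-A response regulator, the 10 higher and 10 lower genes with a symbol and the largest change among those past the threshold in the same direction in all 4 pairs of arrays, and up to 4 past members per list with the smallest p (otherwise the 2 brightest).

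The background level was set after the data had been seen, as the 95th percentile per array of 69 control probe sets whose transcripts do not come from rice and were not among the hybridisation spikes. It was 30.0 and 36.8 on the control arrays and 43.4 and 39.2 on the overexpressor arrays. A transcript at or below it on both arrays of a group has only a bound there, and its fold is given as at least the ratio to that level. As checks of the RNA, the log2 ratio of the 3' to the 5' probe set was 3.36 and 3.10 for actin on the control arrays and 3.06 and 3.01 on the overexpressor arrays, 1.02 and 1.27 against 1.10 and 0.78 for cyclophilin, and -0.50 and -0.56 against -0.57 and -0.59 for ubiquitin.

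The procedure was tested on simulated data with 200 of 28629 probe sets changed, in 20 simulations of 2 arrays per group. With spreads drawn around the fitted trend, 2.6% of 1.5-fold, 30.4% of 2-fold and 69.4% of 4-fold changes were recovered, 6.5% of the calls were false, and a list shifted by -0.5 was found in 20 of 20 simulations with 0 other lists called by camera. With the spread of each probe set taken from the data, recovery was 27.2%, 63.3% and 90.8%, 14.4% of the calls were false, and camera found the shifted list in 20 of 20 simulations and called 7 other lists over all of them. Simulated probe sets varied independently, so the simulations cannot show how often camera calls lists of correlated genes. A far smaller share of probe sets was changed than the 28.5% called in the data, so the percentages may not carry over.

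Alternatives covered the pseudocount, quantile, cyclic loess and median normalization, the filter, the model of the spread, the replicate number as a block, leaving out each array, leaving out probe sets that can hybridise to several transcripts, the size of the fold, and the set test. Scaling to the hybridisation spikes and a filter at the background level were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.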

Results

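Transcript levels in leaves of rice (Oryza sativa, cultivar Nipponbare) were measured on 4 single-colour Affymetrix rice arrays, 2 labelled empty vector control and 2 labelled OsRR6 overexpressor. OsRR6 is a type-A response regulator, a class of proteins induced by the plant hormone cytokinin that dampens the response to it. The comparison asks which leaf transcripts differ when this regulator is expressed from a transgene. The plants were primary transformants raised from callus and grown hydroponically to heading, with 12 h of light at 30 °C and 12 h of dark at 25 °C. They were sampled at an age of 75 days. Values are array signals on a linear scale whose trimmed mean was 500.1 on every array. Group values are means ± SD over 2 arrays. Between 56.9% and 61.7% of the probe sets on an array lay above the signal of control probe sets for transcripts that had not been added. Replicates correlated at 0.988 (control pair) and 0.975 (overexpressor pair) across the tested probe sets on the log2 scale, against 0.931 to 0.938 between groups. The labels do not say whether the replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

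The signal of the OsRR6 probe set was not higher on the arrays labelled overexpressor. The probe set of OsRR6 (RR6, LOC4337372) read 2559 and 2733 on the control arrays and 2264 and 1989 on the overexpressor arrays, a log2 change of -0.32 (SE 0.10, 95% interval -0.56 to -0.07, adjusted p = 0.0597 over all probe sets in limma). Adjusted over the list alone, that is over the type-A regulators, the p-value was 0.0462. The difference passed the threshold over all probe sets after median centring (-0.42, adjusted p = 0.0224), with a filter at the 75th percentile of signal (adjusted p = 0.0496) and without overexpressor replicate 1 (-0.41, adjusted p = 0.00514). After scaling to the hybridisation spikes it was -0.0017. The signal of this probe set was therefore not raised as the group label would have it, and whether it was lower depended on the scaling and the adjustment. Every direction given here is that of the arrays labelled overexpressor. The position of the probe set in the transcript is not given in the sources used here, and a probe set outside the transcribed part of the transgene checks nothing.

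Among the other type-A response regulators, RR1 fell from 618 ± 41.2 to 329 ± 88.7 (log2 change -0.93, SE 0.21, adjusted p = 0.0195). RR2 had a log2 change of -0.52 (adjusted p = 0.0884), RR9 of -0.09 (adjusted p = 0.694) and RR4 of 0.0034 (adjusted p = 0.985), and none of these 3 passed. The signs of RR4 and RR9 changed with the scaling or when an array was left out, and RR9 passed without overexpressor replicate 2 (-0.30, adjusted p = 0.0124). RR5 lay at background in both groups and was not tested. Of the 5 tested type-A regulators 1 was lower and 4 did not pass (2 lower when adjusted over the list alone), and the list did not pass camera, a test of a gene list against all other genes (median -0.32, or -0.0017 after spike scaling, adjusted p = 0.142).

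**Figure D1:**
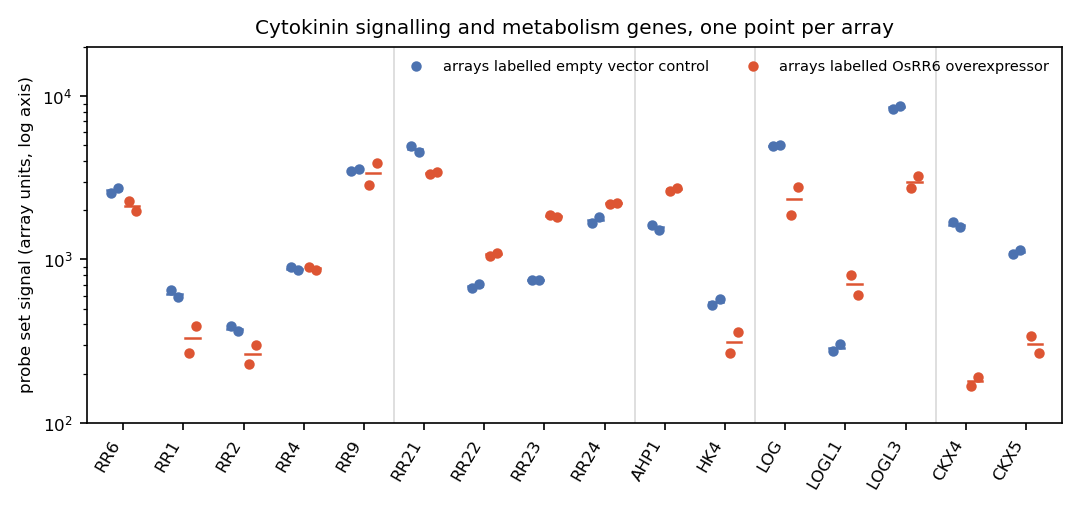
Signal of cytokinin signalling and metabolism genes on each array (array units, log axis). Points are arrays, blue for empty vector control and orange for OsRR6 overexpressor, and horizontal lines are group means of 2 arrays. RR6 lies lower on both overexpressor arrays (2264 and 1989) than on both control arrays (2559 and 2733), and CKX4 drops from a mean of 1633 to 179.6.

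Genes that make, degrade and transmit cytokinin moved in both directions. The cytokinin dehydrogenase genes CKX4 and CKX5, whose enzymes degrade the hormone, fell from 1633 ± 83.8 to 179.6 ± 15.6 (log2 change -3.16, SE 0.14, adjusted p = 0.00019) and from 1112 ± 48.6 to 302 ± 50.4 (-1.88, SE 0.16, adjusted p = 0.000736). Of the 3 tested genes of cytokinin breakdown and conjugation 2 were lower and 1 did not pass, with the same count adjusted over the list alone. The list had a median of -1.88 and a camera adjusted p of 0.0698 (0.469 with an estimated correlation, and 0.0151 with fry). That list passed without control replicate 1 (adjusted p = 0.0404), without overexpressor replicate 1 (0.0296) and after spike scaling (0.00609), each with the preset correlation. Cytokinin activation enzymes were split. LOGL3 fell from 8572 ± 269 to 2995 ± 374 (-1.52, SE 0.10) and LOG by 1.12 on the log2 scale (SE 0.18), while LOGL1 rose by 1.27 (SE 0.18). In that list of 7 tested genes 1 was higher, 2 were lower and 4 did not pass (1 and 3 when adjusted over the list alone, with LOGL5 at -0.51; list adjusted p = 0.172). All 4 tested type-B response regulators, the transcription factors of the pathway, passed: RR23 rose from 746 ± 3.75 to 1852 ± 38.2 (1.31, SE 0.10), RR22 by 0.64 and RR24 by 0.35, and RR21 fell by 0.49. The counts adjusted over the list alone were the same. The list as a whole did not pass camera (median 0.49, adjusted p = 0.282) but passed fry (adjusted p = 0.00934). Of 7 receptors and phosphotransfer proteins, AHP1 rose by 0.77 and the receptor kinase gene HK4 fell by 0.83, with 5 not past in either count (list adjusted p = 0.891).

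The comparison was broad. Of 28629 tested probe sets 4410 were higher and 3760 lower on the arrays labelled overexpressor at an adjusted p of 0.05 (28.5% of those tested). In size, 635 were at least 2-fold higher and 987 at least 2-fold lower in all 4 pairs of arrays. An exact permutation test of 2 against 2 arrays cannot go below a two-sided p of 0.33. Leaving out control replicate 1 gave 1412 higher and 1607 lower probe sets, and leaving out control replicate 2 gave 1519 and 1721. The spread was then taken from the overexpressor pair, whose median difference on the log2 scale was 0.203 against 0.115 in the control pair. The balance of directions depended on the scaling. Median centring gave 3030 higher and 4631 lower, with 464 and 1208 at least 2-fold apart in all 4 pairs. Scaling to the hybridisation spikes gave 11617 higher and 2108 lower, with 1582 and 562 in that count. The 27 spike probe sets had a mean log2 change of -0.32 on the overexpressor arrays (25 of them lower in every pair), and this scaling moved the median change of the tested probe sets from 0.08 to 0.40.

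The largest decreases among named genes past the test were those of the anther transcripts RTS and C6. RTS, a gene of the tapetum of the anther, read 3873 ± 242 on the control arrays and 7.3 ± 4.95, within background, on the overexpressor arrays, which is at least 86.4-fold lower (log2 change -8.55, SE 0.33, adjusted p = 0.000164). C6, which encodes a lipid transfer protein of anthers, fell from 5485 ± 279 to 68.4 ± 63.9 (-6.61, SE 0.61, adjusted p = 0.00103), with 113.6 on overexpressor replicate 1 and 23.2, within background, on replicate 2. RAFTIN1 fell from 991 ± 39.5 to 95.9 ± 51.6 (-3.43, SE 0.35). The other largest decreases were those of NIP4-1 (-3.59, SE 0.32), the type 2C protein phosphatase genes PP2C68 (-3.27, SE 0.16) and PP2C30 (-2.72, SE 0.12), CKX4, the homeodomain gene HOX24 (-2.93), the linalool synthase gene LIS (-2.84) and the chitinase gene Cht6 (-2.80).

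Among the increases, BURP16 rose from background (7.4 ± 4.38) to 1233 ± 1260.3, at least 23.3-fold higher (log2 change 6.34, SE 0.81, adjusted p = 0.00305), with 2124 on overexpressor replicate 1 and 341.7 on replicate 2. The isocitrate lyase gene ICL (4.03, SE 1.12, adjusted p = 0.0389) and LEA19, a late embryogenesis abundant protein gene (3.92, SE 0.55), also differed widely between the overexpressor arrays. GRXC1, a glutaredoxin gene, rose from 90.5 ± 3.04 to 1346 ± 436 (3.80, SE 0.24) and Agglutinin, a lectin gene, from 166 ± 11.5 to 1907 ± 93.8 (3.50, SE 0.13). CYP76M7 rose by 2.74 and the dehydrin gene RAB21 from 263 ± 31.8 to 1794 ± 533 (2.73, SE 0.22), followed by GER2 (2.70), Chib3H-a (2.56) and HOX12 (2.36).

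**Figure D2:**
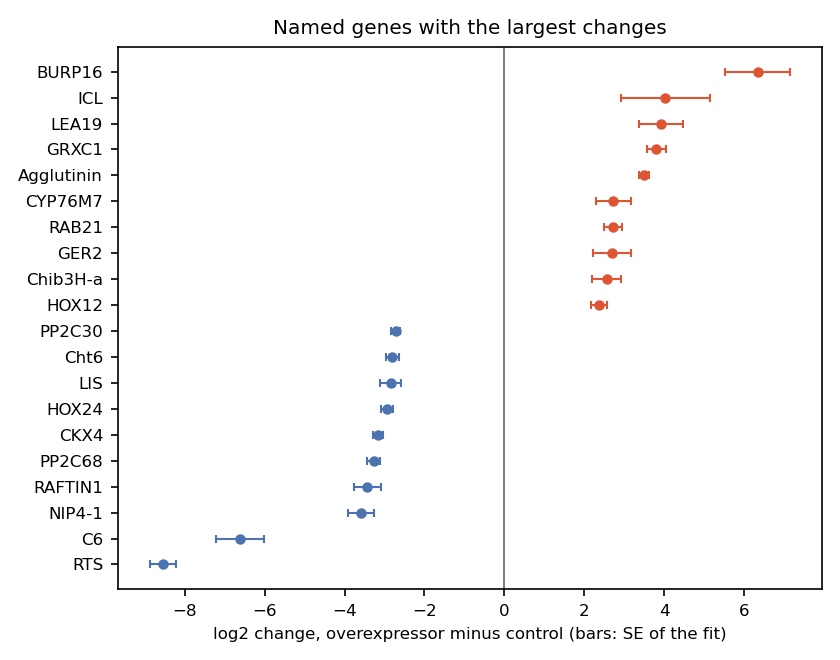
Log2 change (arrays labelled overexpressor minus control) of the 10 named genes with the largest increase and the 10 with the largest decrease among those past the test. Points are differences of means of 2 arrays per group and bars are the SE of the limma fit. RTS and C6 lie farthest to the left (-8.55 and -6.61) and BURP16 farthest to the right (6.34), and for RTS and BURP16 these are values with a group at background.

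Of 33 gene lists fixed before the data were examined 32 could be tested, and 11 passed camera with a preset correlation between genes, 8 lower and 3 higher. With an estimated correlation 0 of the 32 lists passed (smallest adjusted p = 0.469, 0 at an unadjusted p of 0.05). That form of camera rests on 2 residual degrees of freedom here, so it could hardly pass any list, and its result decides little. The test fry, which asks whether the genes of a list move one way, passed 15, of which 9 were among the 11. Of the 6 others, type-B response regulators (fry adjusted p = 0.00934) and cytokinin receptors and phosphotransfer proteins (0.0434) were higher. Lower were iron and phosphate deficiency (0.00865), cytokinin breakdown (0.0151), cytokinin synthesis (0.0466) and homeobox and meristem genes (0.0466). A list said to pass or not to pass is judged by camera with the preset correlation unless named otherwise.

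Jasmonate synthesis and response was the list with the smallest p in camera with the preset correlation, though not in the 2 other set tests. Of its 26 tested genes 20 were lower, 1 was higher and 5 did not pass (22, 2 and 2 adjusted over the list alone), with a median of -0.86 (-0.54 after spike scaling) and a camera adjusted p of 3.33e-09 (adjusted p = 0.469 with an estimated correlation). JAZ8 and JAZ11, which encode repressors of jasmonate signalling, fell from 6341 ± 313 to 1459.8 ± 7.85 (-2.12, SE 0.08) and from 8167 ± 507 to 3439 ± 72.3 (-1.25, SE 0.08). The lipoxygenase gene LOX5 fell by 1.02 and the allene oxide cyclase gene AOC3, of jasmonate synthesis, by 0.95.

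Camera with the preset correlation placed the anther, flowering time and floral identity, and vascular lists lower. In the anther and pollen list 7 of 10 tested genes were lower and 3 did not pass in either count (median -1.36, adjusted p = 0.000132, and adjusted p = 0.469 with an estimated correlation). C4 fell from 4038 ± 109 to 655 ± 211 (-2.66, SE 0.21). Of 22 tested flowering time and floral identity genes 8 were lower and 14 did not pass (9 lower and 1 higher adjusted over the list alone; median -0.49, or -0.17 after spike scaling; adjusted p = 0.00137, and adjusted p = 0.469 with an estimated correlation and 0.0603 with fry). The florigen gene Hd3a fell by 1.52 (SE 0.20), MADS14 from 4877 ± 40.2 to 2663 ± 433 (-0.88, SE 0.12), MADS26 by 0.97 and MADS56 by 0.89. Of the 7 genes of the leaf sheath and stem vascular list 6 were lower and 1 was higher in both counts (median -0.46, or -0.15 after spike scaling, adjusted p = 0.0101, and adjusted p = 0.469 with an estimated correlation). The cellulose synthase gene CESA7, of secondary walls, fell by 0.46, BC1L9 by 1.21 and BC1 by 0.79, while BC1L2 rose by 1.26.

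The lists of cell division and ribosomal genes were placed higher by camera with the preset correlation, and part of their genes passed. In the cell cycle and DNA replication list 16 of 28 tested genes were higher, 0 were lower and 12 did not pass (20 higher adjusted over the list alone), with a median of 0.82 and an adjusted p of 0.00117 (adjusted p = 0.639 with an estimated correlation and 0.11 with fry). PCNA, the sliding clamp of DNA replication, rose from 998 ± 73.2 to 1967 ± 254 (0.97, SE 0.13), the helicase gene MCM2 from 315 ± 24.5 to 827 ± 206 (1.36, SE 0.20), and the D-type cyclin genes CYCD3-1 and CYCD4-1 by 1.42 (SE 0.19) and 2.02 (SE 0.31). Of the 6 histone genes 5 were higher and 1 did not pass (6 higher adjusted over the list alone; median 0.68, adjusted p = 0.00742, and adjusted p = 0.502 with an estimated correlation). All 4 named members are H2B genes, with H2B.7 at 0.73, H2B.6 at 0.70, H2B.10 at 0.68 and H2B.11 at 0.49. The cytosolic ribosomal protein list had a smaller median, a difference between lists that was not tested. Of 23 tested genes 10 were higher, 0 were lower and 13 did not pass (14 higher adjusted over the list alone; median 0.24, or 0.14 after median centring and 0.55 after spike scaling; adjusted p = 0.0052, and adjusted p = 0.469 with an estimated correlation). RPL18 rose from 5175 ± 9.62 to 7999 ± 308 (0.63, SE 0.07), RPS7 by 0.39, RPS4 by 0.36 and RPL30 by 0.33.

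**Figure D3:**
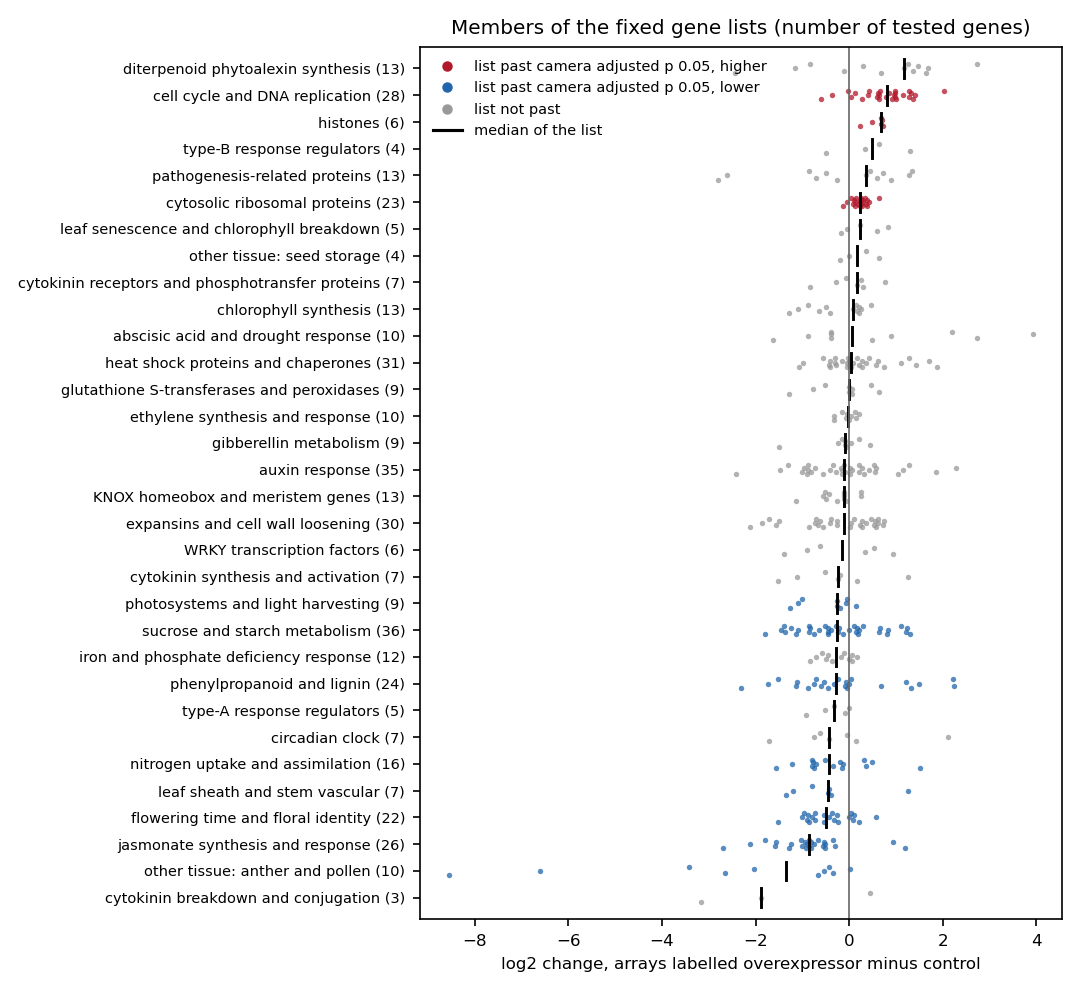
Log2 change (arrays labelled overexpressor minus control) of the tested members of the 32 gene lists. Each point is a gene, the vertical line is the median of the list, and red and blue mark lists past camera with a preset correlation in the higher or lower direction. The medians run from -1.88 to 1.17.

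The photosystem list was placed lower relative to the other genes on these arrays, and 3 of its genes passed. Rubisco activase, rcaA1, fell from 25244 ± 332 to 11764 ± 439 (-1.10, SE 0.07), the photosystem I subunit gene PSAG1 from 3469 ± 254 to 1446 ± 155 (-1.26, SE 0.11) and PSB28 by 1.02. Of the 9 tested genes of this list, which also holds Rubisco genes, 3 were lower and 6 did not pass (4 lower adjusted over the list alone, with CAB2R at -0.25; median -0.25, adjusted p = 0.00778, and adjusted p = 0.469 with an estimated correlation). The call ended under quantile normalization (median -0.09, adjusted p = 0.0787) and cyclic loess (-0.11, adjusted p = 0.114), and after spike scaling the median was 0.06. In chlorophyll synthesis, PORA fell from 4546 ± 265 to 1859.8 ± 97.4 (-1.29, SE 0.09), GluTR by 1.09, CHLH by 0.64 and LYL1 by 0.51. That list had 6 lower, 1 higher and 6 not past of 13 genes in both counts. Its median was 0.08 (-0.02 after median centring and 0.39 after spike scaling) and its mean -0.25, and it did not pass (lower, adjusted p = 0.143).

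Nitrogen and carbon metabolism and phenylpropanoid lists held both lower and higher genes. The nitrate reductase gene NIA1 fell from 4753 ± 15.9 to 2049.7 ± 36.5 (-1.21, SE 0.08) and the glutamine synthetase genes GLN1-1 and GLN2 fell by 0.76 and 0.51, whereas the glutamate synthase gene GLT2 rose from 1509.7 ± 145 to 4306 ± 138 (1.51, SE 0.10). Of 16 tested nitrogen genes 6 were lower, 1 was higher and 9 did not pass (7, 2 and 7 adjusted over the list alone; median -0.43, or -0.11 after spike scaling; adjusted p = 0.0149, and adjusted p = 0.469 with an estimated correlation). The sucrose and starch list had 13 lower, 6 higher and 17 not past of 36 genes (16, 6 and 14 adjusted over the list alone; median -0.25, or 0.06 after spike scaling; adjusted p = 0.0187, and adjusted p = 0.469 with an estimated correlation). Its invertase gene CIN1 fell from 6215 ± 89.2 to 2419.7 ± 150.3 (-1.36, SE 0.08), SSII-2 by 1.39, SS1 by 1.23 and SWEET2a by 0.86. Among 24 phenylpropanoid and lignin genes 10 were lower, 4 were higher and 10 did not pass in both counts (median -0.28, or 0.04 after spike scaling; adjusted p = 0.0209, and adjusted p = 0.469 with an estimated correlation). CAD6 (-2.31, SE 0.19), CAD3 (-1.74, SE 0.13) and the phenylalanine ammonia-lyase gene PAL06 (-1.52, SE 0.09) fell, and the laccase gene LAC7 rose (2.22, SE 0.14). Without overexpressor replicate 2 the nitrogen list (adjusted p = 0.0664) and the phenylpropanoid list (0.111) lost the call. The latter also lost it under quantile normalization (0.0502) and cyclic loess (0.0618), where its median stayed at -0.31 in both, and the sucrose and starch list with the mean of the probe sets of a gene (0.0559).

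Several lists held strong changes that ran both ways, and did not pass. In the abscisic acid and drought list 3 of 10 genes were higher, 3 lower and 4 not past (3, 4 and 3 adjusted over the list alone), and the list's median (0.05) and mean (0.66) were positive while camera placed it lower (adjusted p = 0.913). After median centring the median was -0.05 and camera placed the list higher (adjusted p = 0.82). RAB16B rose by 2.20, and Dhn1 fell from 10238 ± 206 to 3364 ± 728 (-1.62). Diterpenoid phytoalexin genes had 4 higher, 2 lower and 7 not past of 13 in both counts (median 1.17, adjusted p = 0.553). CYP71Z7 rose by 1.65, while CYP71Z6 fell from 1199 ± 108 to 223 ± 62.9 (-2.44) and KSL5 by 1.15. Pathogenesis-related genes had 4 higher, 4 lower and 5 not past of 13 (5, 4 and 4 adjusted over the list alone), with a median of 0.37 (0.68 after spike scaling) and a mean of -0.16. The direction of this list in camera was lower (adjusted p = 0.775), and higher after median centring (adjusted p = 0.969). Its chitinase genes Chia1d (-2.61) and Cht6 fell while Cht2 (1.35) and Cht11 (0.60) rose. Of 6 WRKY genes 2 were higher, 3 lower and 1 not past in both counts (median -0.15, or 0.17 after spike scaling, adjusted p = 0.642), with WRKY62 at 0.94, WRKY24 at -1.38, WRKY71 at -0.89 and WRKY51 at -0.63. The heat shock and chaperone list had 9 higher, 3 lower and 19 not past of 31 (9, 5 and 17 adjusted over the list alone; median 0.03, or -0.07 after median centring and 0.34 after spike scaling; adjusted p = 0.786). Its member hsp17.9 rose from 1239 ± 64.5 to 4593 ± 537 and HSP26.2 by 1.28, and CLPD1 fell by 0.98 and HSP16.9B by 1.08.

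Clock, growth and hormone lists did not pass camera on the deposited scale either, and their genes past the threshold differed in number and size. The clock gene PCL1 rose from 1263 ± 122 to 5479.6 ± 783 (2.11, SE 0.13) while CCA1 fell from 1946 ± 10.5 to 599 ± 105 (-1.70, SE 0.14), PRR73 by 0.75 and PRR95 by 0.62. This made 4 lower, 1 higher and 2 not past of 7 clock genes in both counts (median -0.43, or -0.11 after spike scaling, adjusted p = 0.142). Of 35 auxin genes 8 were higher, 10 lower and 17 not past (8, 11 and 16 adjusted over the list alone; median -0.10, or 0.21 after spike scaling; adjusted p = 0.214). SAUR39 (2.27) and IAA14 (1.86) rose, and PIN5a (-1.48) and GH3.5 (-0.88) fell. Expansin and wall loosening genes had 3 higher, 12 lower and 15 not past of 30 (6, 13 and 11 adjusted over the list alone; median -0.12, adjusted p = 0.143, or median 0.19 and adjusted p = 0.0281 in the lower direction after spike scaling). EXPA5 fell from 1419 ± 93.8 to 390.2 ± 33.2, EXPB2 by 1.57 and XTH8 by 0.63. Gibberellin genes had 1 higher (gid1, 0.45), 1 lower (CPS1, -1.49) and 7 not past of 9 in both counts (adjusted p = 0.564). Of 10 ethylene genes ETR3 was lower (-0.33) and 9 did not pass (0 past in limma adjusted over the list alone, 2 lower and 0 higher at an unadjusted p of 0.05; list adjusted p = 0.479). In the homeobox and meristem list OSH1 (-0.44) and WOX11 (-1.14) were lower and 11 of 13 did not pass (0 past in limma adjusted over the list alone, 3 lower and 0 higher at an unadjusted p of 0.05; list adjusted p = 0.0867).

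The remaining lists did not pass camera either. Senescence and chlorophyll breakdown genes had 2 higher, OSL2 (0.60) and RCCR1 (0.83), and 3 not past of 5 in both counts (adjusted p = 0.479, and 0.0456 without overexpressor replicate 2). Iron and phosphate deficiency genes had 3 lower and 9 not past of 12 in both counts (median -0.28, or 0.04 after spike scaling, adjusted p = 0.0666). The lower genes were the phosphate transporter genes Pht1;8 (-0.83) and Pht1;4 (-0.59) and NAAT1 (-0.37). Glutathione S-transferase and peroxidase genes had 1 higher (GSTU6, 0.63), 3 lower (GSTF1, -1.30, GSTZ5, -0.51, and PRX74, -0.78) and 5 not past of 9 in both counts. The median was 0.0021, the mean -0.15 and the adjusted p 0.419, in the lower direction. Of 4 seed storage genes GLB1 was higher (0.35) and 3 did not pass in both counts (adjusted p = 0.749). The root list had 1 member with a probe set, CASP1, which read 34.5 ± 29.1 and 24.7 ± 23.2 and was too dim to be tested.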

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

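Scaling to the hybridisation spikes and the filter at the background level were chosen after the data had been seen, and all other alternatives before. The naming rule takes mostly genes past the threshold, so a high share past it and a stable direction follow in part from the rule. Of 123 named genes with a test besides OsRR6, 118 passed, and all 118 kept their direction in every alternative that tested them. Of these, 87 stayed past the threshold in all alternatives that tested them, and 31 lost the call in at least 1. Leaving out an array takes the spread from the other pair, so a call kept there says little about the group left with 1 array. Without the trend of the spread, 2580 probe sets were higher and 2461 lower, against 4410 and 3760. Spike scaling gave 11617 and 2108. It adds the same amount to every probe set of an array, and that amount follows the spikes, which had a mean log2 change of -0.32 on the overexpressor arrays. Why the spikes were lower there was not tested. The count of 1622 probe sets at least 2-fold apart in every pair became 4379 at 1.5-fold, 481 at 3-fold, 3302 with no filter and 764 with a filter at the 75th percentile, where the number of probe sets counted differs by construction. The 11 lists past camera became 0 with an estimated correlation and 15 with fry, 9 of the 11 and 6 others. OsRR6 passed at -0.42 after median centring and at -0.32 with the filter at the 75th percentile, where fewer probe sets were adjusted for, and its adjusted p over all alternatives lay between 0.00514 and 0.991. With 1 array left out, the lone array of a group was assumed to vary like the other pair: OsRR6 lay between -0.41 and -0.22, the higher probe sets between 1412 and 6152, the lower between 1607 and 5233, those 2-fold in every pair between 2186 and 2734, and the lists past camera between 10 and 12. RR4 (0.0034) turned to -0.046 under quantile normalization, -0.056 under cyclic loess, -0.098 after median centring, -0.034 without control replicate 2 and -0.026 without overexpressor replicate 1, and lay at 0.041 without control replicate 1 and 0.32 after spike scaling (adjusted p = 0.0564). RR9 (-0.09) turned to 0.13 without overexpressor replicate 1 (-0.30 without overexpressor replicate 2, where it passed, adjusted p = 0.0124) and 0.23 after spike scaling, and CAB2R (-0.25) to 0.064 after spike scaling. None of these 3 passed where its sign turned, and the cause was not tested apart from the construction of the spike scaling. Same-numbered arrays did not deviate together (correlation -0.02), and with the replicate block 4236 probe sets were higher and 3695 lower, OsRR6 was at -0.32 (adjusted p = 0.0805) and 11 lists passed. Signals at background limit folds to bounds for RTS and BURP16.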

Other observations

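The tests of floral organ identity genes, of scaling, of exchanged labels, of the cytokinin response and of the time of day, and the grouping of genes by symbol, were chosen after the results had been seen. The tests of meiosis genes and of growth-regulating factors were set before the values of those genes were seen. The readings of the meiosis genes, of the cytokinin response and of the time of day as leaving the question open were decided after their values had been seen.

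Gene families outside the fixed lists, grouped by the start of their symbols, held many changes, and no family passed after adjustment. Among all 2228 tested genes with a symbol 917 had a probe set past the threshold, so many changes in a family are not particular to it. Of 16 families with at least 10 tested genes, 0 passed camera after adjustment (6 at an unadjusted p of 0.05, and 0 in either count with an estimated correlation). Genes with symbols starting with PP, mostly type 2C protein phosphatases, which include negative regulators of abscisic acid signalling, had 18 lower and 4 higher of 54 (median -0.09, or 0.23 after spike scaling; adjusted p = 0.061). Besides PP2C68 and PP2C30, OsPP2C48 fell from 1824 ± 50.7 to 629 ± 93.6 (log2 change -1.54, SE 0.13, adjusted p = 0.000804) and OsPP2C40 from 5960.2 ± 30.2 to 1989 ± 428 (-1.60, SE 0.15, adjusted p = 0.001), while OsPP2C73 rose from 377.0 ± 16.3 to 1171 ± 336 (1.60, SE 0.20, adjusted p = 0.00297). Membrane proteins of the CASPL family had 11 higher and 1 lower of 18 (median 0.46, adjusted p = 0.061), with OsCASPL1B1 rising from 152 ± 0.92 to 382 ± 15.1 (1.31, SE 0.17, adjusted p = 0.00336).

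Calcium signalling and potassium transporter genes were among the other families. Of 14 calcium-dependent protein kinase genes (CPK) 6 were lower and 1 was higher (median -0.31, or 0.0074 after spike scaling; camera adjusted p = 0.0913), CPK7 falling from 3964 ± 109 to 1875 ± 28.2 (-1.08, SE 0.08, adjusted p = 0.000606). The calcium signalling family CIPK had 5 higher and 6 lower of 22 (median -0.02, or 0.30 after spike scaling; camera adjusted p = 0.486). The CML family had 4 higher and 6 lower of 20 (median -0.26, or 0.05 after spike scaling; camera adjusted p = 0.0913). Differences between these families were not tested. Of 20 potassium transporter genes (HAK) 8 were lower and 3 higher (median -0.10, or 0.22 after spike scaling; adjusted p = 0.119), with HAK27 falling from 2824 ± 83.4 to 627 ± 92.8 (-2.17, SE 0.13, adjusted p = 0.000335). These genes were chosen after their values had been seen.

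Anther transcripts stood out in leaf samples, with C6, C4 and RTS at 5485, 4038 and 3873 on the control arrays, and 11 of the 12 members of the list, none of them in another list, were above background on both control arrays and 8 on both overexpressor arrays. Quantile and cyclic loess normalization moved the median change of all tested probe sets only from 0.08 to 0.04 and 0.02. The median of the list stayed at -1.39 and -1.42. The list stayed past camera with the preset correlation (highest adjusted p = 0.000126) but did not pass with an estimated correlation (adjusted p = 0.469). With falls this large the call could hardly have ended under these 2 normalizations, so this test of scaling decides little. Flower tissue in the control samples, which were taken at heading, was left open. The 9 tested floral organ identity genes, of 11 with a probe set, were part of the flowering list already seen as lower. Their mean log2 change was -0.475 (SE 0.127 over genes, 2 lower and 0 higher), or -0.16 after spike scaling. Meiosis and early anther genes went the other way (0.621, SE 0.179 over 5 genes, 1 higher and 0 lower, or 0.94 after spike scaling), which had been set as a result against such tissue. The 5 genes, however, read only 57.3 to 444 on the control arrays, where leaf signal may hide a small share of flower tissue, and such tissue may be past meiosis. Only 5 of 10 meiosis and early anther genes with a probe set were bright enough to be tested. The tested genes of both sets were above background on both arrays of each group. The brightness filter lay above background, so this was nearly fixed in advance and decides nothing. Flower tissue in the overexpressor samples was not excluded either. The SEs over genes do not measure the spread between samples. Flower tissue in either group and a lower level of the anther transcripts in the leaf therefore cannot be told apart here, because no sample of flowers was among the arrays.

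The OsRR6 probe set was not higher on the arrays labelled overexpressor. The 95% interval of the log2 change ran from -0.56 to -0.07, which leaves out a 2-fold excess on the arrays labelled control. If the probe set reads the transgene, this argues against an exchange of the labels with overexpression of at least 2-fold. If it lies outside the transgene, it checks nothing. The position of the probe set is unknown, so an exchange was left open. A weaker cytokinin response was left open: the other type-A regulators and the cytokinin dehydrogenases had a mean log2 change of -0.874 (-0.56 after spike scaling) and passed fry at an unadjusted 0.05, but the median was -0.52 and the mean rested on CKX4 and CKX5, which had been seen to fall before the set was drawn up. The 4 other type-A regulators alone had a mean of -0.38 (-0.07 after spike scaling) and did not pass fry. Lower cytokinin content was not tested.

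Camera with the preset correlation placed the cell cycle, histone and ribosomal lists higher and the photosystem list lower, none of which passed with an estimated correlation (adjusted p = 0.639, 0.502, 0.469 and 0.469). Scaling was argued against for the higher lists with the preset correlation, whose highest adjusted p under quantile and cyclic loess normalization was 0.0045. For the photosystem list scaling may account for the call, which ended under cyclic loess (adjusted p = 0.114) and quantile normalization (0.0787) as its median moved from -0.25 to -0.11 and -0.09. A later time of day at harvest was left open: PCL1 was higher (2.11) and CCA1 (-1.70), PRR73 (-0.75) and PRR95 (-0.62) lower, while the upper ends of the intervals of the evening genes GI and PRR1 reached at most 0.317. More growing tissue in the samples labelled overexpressor, as a sampling difference or as an effect of the transgene, may explain the higher lists. Growth-regulating factors had a mean log2 change of 0.598 (SE 0.131 over 9 tested genes, 3 higher and 0 lower), or 0.91 after spike scaling. The SE over genes does not measure the spread between samples. The overexpressor arrays lay far apart for GRF10 (123 ± 5.44 to 327 ± 180) and GRF7 (210 ± 22.2 to 469 ± 170). GRF11 varied alike in both groups (3364 ± 255 and 3847 ± 253). Expansin genes, however, had a median of -0.12 (0.19 after spike scaling). The homeobox and meristem list had 0 higher, 2 lower and 11 not past of 13 genes (median -0.12, or 0.20 after spike scaling).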
